A study of Mus musculus with 24 samples.

How the data were processed

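Mouse embryonic stem cells (ES) were differentiated into neuronal progenitors (NP) and terminal neurons (TN), and total RNA, extracted with TRIzol and cleaned on RNeasy columns, was hybridized to Affymetrix arrays. There were 24 arrays on 2 platforms. On the platform with 18 arrays, the cells were of the strain Black Agouti 129 and fell into 6 groups of 3 arrays: ES and NP labelled RESTko or RESTwt, and TN labelled RESTko or RESThet. On the other, 6 arrays came from wildtype cells of a mixed 129Sv-C57Bl/6 strain, 2 at each of the 3 stages. The labels call the arrays biological replicates but do not say whether they came from separate cultures, so every p-value measures only the spread between these arrays.

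The values deposited by the authors are log2 probe-set signals. The labels name the software oligo 1.14.0; the background correction, summarization and normalization, and whether all arrays of a platform were normalized together, are not given in the sources used here. The values were used as deposited. The quantiles of arrays of the same stage nearly coincided. On the 18 arrays the median signal was 5.02 to 5.07 at ES, 5.19 to 5.26 at NP and 5.41 to 5.49 at TN, and on the 6 arrays it was 3.83 to 3.95. Arrays have no read depth, and their number limits the precision: the median standard error of a difference between genotypes was 0.10 on the log2 scale.

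Probes were given gene symbols from a table of probes and genes, updated by gene number to the names of the mouse annotation GRCm38.p6, which also gave each gene's chromosome. Of 35556 probes on the larger platform, 21789 carried a single symbol, 1621 several and 12146 none; on the other, 34958 of 45101 carried a single symbol. Probes with no symbol or several were tested only in fits of all probes together. A gene was represented by its probe with the highest mean over all arrays of its platform, which gave 19938 and 18194 genes. The platforms were never combined in a fit.

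A linear model with a mean for each group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with their defaults) to all arrays of a platform. The moderated test of limma is two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison. Genes with an adjusted p under 0.05 were called. The comparisons were RESTko minus RESTwt at ES and at NP, RESTko minus RESThet at TN, the differences between these effects (interactions), the stage steps within a genotype, and the stage steps of the mixed-strain course. No replicate block was used, since the labels do not say that a letter marks a shared batch. The model, comparisons, gene lists, alternatives and rule for naming genes were chosen before the data were examined.

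The named genes are Rest and, for each comparison of genotypes, the 8 genes with the largest positive and the 8 with the largest negative difference among called genes whose groups of arrays do not overlap. For each interaction and stage step the number is 5 in each direction. Predicted genes, receptors of the olfactory system and small RNAs were left out. Up to 4 called members of each gene list with the largest difference were named as well, or up to 2 members with their values where none was called. In the comparisons of genotypes, all 3 arrays of a group therefore lie on the same side of all 3 of the other for each gene named by its rank. For an interaction, the condition was that the differences between single arrays at one stage do not overlap those at the other.

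Of 35 gene lists fixed beforehand, 34 had at least 5 measured members on the larger platform and were tested with camera of limma at its preset correlation of 0.01, adjusted over lists and comparisons within each of 3 families (the comparisons of genotypes, the interactions and stage steps, and the course). The list of genes of the 2-cell state had 4 of 11 members measured there and was not tested. The list of RE1 targets holds genes with the DNA element that REST binds, from general knowledge and not from these arrays. It may not hold all such genes, so genes outside it can be targets too. For each list, called members were counted after adjustment over all genes and adjusted over the list alone. The tests were repeated with a correlation estimated from the arrays, and with fry, which asks whether the members move one way on balance without a comparison with other genes. With the estimated correlation 0 list calls remained at ES, NP and TN, against 6, 13 and 10 with the preset. Of the stage steps, the list of retinoic acid response genes held with it between NP and ES, in RESTwt and in RESTko cells.

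Overlaps between stages and with the course were tested with Fisher's exact test (two-sided) over genes, which are not independent replicates, and their p-values were adjusted within each of these families. Other settings were a block for the replicate letter, fits on the compared groups alone, omission of the dimmest 30% of genes, the mean over a gene's probes, every probe, quantile normalization again, subtraction of array medians, eBayes with trend and robust, array weights, each array left out in turn, a 2-fold minimum and an adjusted p under 0.01. On the larger platform the block was fitted to the arrays of the compared stages alone. Omission of the genes of chromosomes 8 and X, neuronal lists without RE1 targets, and a plain letter block in the course were added after the data were seen. The model was tested on simulated data with 200 changed genes: a change of 1 on the log2 scale was called in 97.0% of such genes at ES, 97.0% at NP and 98.5% at TN, and a change of 0.5 in 68.7%, 67.2% and 64.2%. Recovery was lower for the interactions (86.6% and 85.1% at a change of 1, 41.8% and 19.4% at 0.5) and in the course, with 2 arrays per stage (44.8%, 56.7% and 49.3% at a change of 1).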

Results

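Expression of 19938 genes was measured on 18 arrays of cells labelled as knock-out, heterozygous or wildtype for REST, the repressor that keeps neuronal genes silent outside neurons, at 3 stages of differentiation in vitro, with 3 arrays in each of 6 groups. A further 6 arrays followed 18194 genes through the same stages in wildtype cells of a mixed strain, with 2 arrays at each stage. Arrays of the same group on the larger platform correlated across genes with Pearson's r of 0.992 to 0.998, and arrays of different groups with 0.763 to 0.995. Values below are differences of log2 signals with their standard error (SE) from limma, and group means with their SD.

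The Rest probe set did not follow the genotype labels at every stage. At ES, Rest fell by 0.36 (SE 0.07, adjusted p = 0.00234), from 8.96 ± 0.02 in the arrays labelled RESTwt to 8.61 ± 0.07 in those labelled RESTko (n = 3 each, limma). At NP the means were 7.48 ± 0.03 and 7.47 ± 0.09 (adjusted p = 0.958, limma). At TN, Rest was higher in the arrays labelled RESTko, at 7.37 ± 0.09, than in those labelled RESThet, at 7.03 ± 0.03 (difference 0.34, adjusted p = 0.0187, limma), a call that ended on leaving out any of 4 arrays (adjusted p up to 0.105, without RESTko array c). The array holds 1 probe set for Rest, and the sources used here do not give which exon was deleted or which exons the probes cover. The direction of every comparison between genotypes rests on the labels. Rest fell between ES and NP by 1.48 in RESTwt cells, and it fell in RESTko cells too.

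The comparison at ES asks which genes REST keeps low in pluripotent cells. Neuronal genes were higher in the arrays labelled RESTko, led by Scg3, a protein of secretory granules, at 8.18 ± 0.09 against 3.39 ± 0.11 (difference 4.79, SE 0.13, 27.7-fold, adjusted p = 1.14e-13, limma, n = 3 each). The synaptic vesicle protein gene Syp rose 6.58-fold (adjusted p = 2.73e-11) and Nrsn1, expressed in neurons, 5.60-fold. Chga rose by 2.25, Syt4 by 2.23, Gdap1 by 2.22, Anxa3 by 2.28 and Calml4 by 2.59. The largest decreases lay in Smc1b, a cohesin subunit of meiosis (-2.03, adjusted p = 4.89e-07), Kbtbd11 (-1.90), Cyct (-1.88), Dnajc5g (-1.87), Ct55 (-1.84), Nlrp4f (-1.62), Ogdhl (-1.59) and Pla2g4a (-1.55).

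Of 52 RE1 targets, 22 rose at ES and 0 fell, or 25 and 0 adjusted over the list alone, with a median difference of 0.23 (camera adjusted p = 2.25e-19; adjusted p = 0.365 with an estimated correlation). Of 25 pan-neuronal genes, 10 rose and 0 fell (11 and 1 adjusted over the list alone), among them Snap25 (2.13), Elavl3 (1.28), Crmp1 (1.28) and Nefm (1.27). The camera adjusted p for this list was 2.36e-06 (adjusted p = 0.777 with an estimated correlation). Of 38 synaptic vesicle genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), including Unc13a (2.12), which primes vesicles for release (camera adjusted p = 7.31e-07; adjusted p = 0.596 with an estimated correlation). Of 29 genes of dense-core granules, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with Vgf at 1.49 and Ptprn at 1.43 (camera adjusted p = 5.78e-05; adjusted p = 0.521 with an estimated correlation). These lists share members with the RE1 list: without them, 7 of 21 pan-neuronal genes (median 0.20), 5 of 29 synaptic vesicle genes (0.014; 1 fell) and 4 of 22 dense-core genes (0.06) were called higher.

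Genes of other lineages also differed at ES. Of 24 endoderm and epithelial markers, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with the keratins Krt8 (1.60), Krt18 (1.55) and Krt19 (1.25) and the adaptor Dab2 (1.20) the largest. The camera adjusted p was 0.0214 (adjusted p = 0.777 with an estimated correlation). Of 21 mesoderm and muscle genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone), among them the smooth muscle genes Tagln (1.49) and Acta2 (1.19). The mesoderm and muscle list did not pass its test (camera adjusted p = 0.749). Of 14 p53 and apoptosis genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), including Plk2 (0.82), Perp (0.61), the p53 inhibitor Mdm2 (0.45) and Zmat3 (0.44). The camera adjusted p was 0.000317 (adjusted p = 0.487 with an estimated correlation). Of 27 pluripotency genes, 0 rose and 4 fell (1 and 4 adjusted over the list alone): Zfp42 (-0.99), Fgf4 (-0.60), Prdm14 (-0.51) and Tcl1 (-0.47). The pluripotency list did not pass its test (camera adjusted p = 0.434). Leaving out single arrays ended the calls of Zfp42 (adjusted p = 0.129 without RESTwt array c), Prdm14 (0.111 without RESTwt array c), Tcl1 (0.102 without RESTko array b) and Acta2 (0.0904 without RESTko array a).

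At ES 1842 genes were called, 1034 higher and 808 lower in the arrays labelled RESTko, of which 149 differed at least 2-fold. The arrays of the groups did not overlap for 29.4% of genes, against 10% by chance. Genes of chromosome 8 made up 30.9% of the lower calls, with a median difference of -0.25 over 567 genes in the upper part of the signal range, against 0.00 to 0.05 on the other autosomes. The lower genes named above were not sorted by chromosome, so this shift may be part of some of their differences. Without RESTwt array c the count was 1190 and without RESTko array a 1199. Array weights gave 3430.

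**Figure D1:**
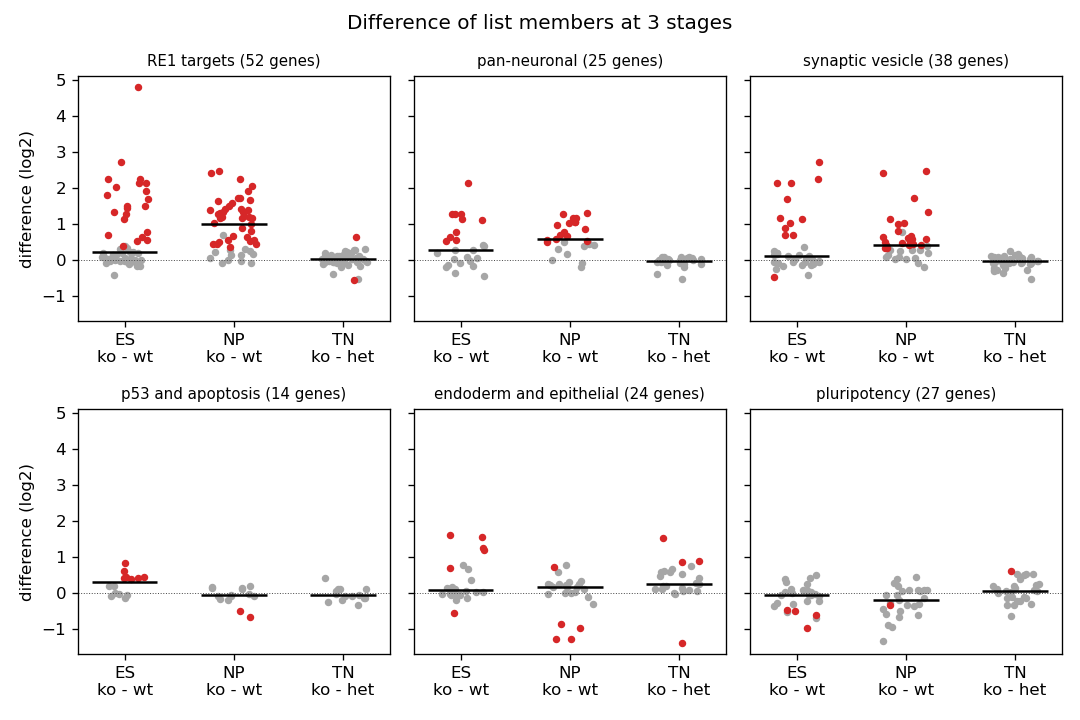
Log2 difference (RESTko minus RESTwt at ES and NP, RESTko minus RESThet at TN, 3 arrays per group) of each measured member of 6 gene lists, by stage; red points have an adjusted p under 0.05, grey points do not, and bars are medians. RE1 targets sit at a median of 0.23 at ES, 1.00 at NP and 0.03 at TN.

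The comparison at NP asks the same of committed progenitors. Neuronal genes were higher in the arrays labelled RESTko: Cplx1, a regulator of vesicle release, 5.30-fold (difference 2.41, adjusted p = 6.27e-12), Scg3 4.73-fold (2.24, adjusted p = 8.86e-09), the vesicle calcium sensor Syt4 by 2.46 and Nrsn1 by 2.48. Nmnat2, needed for axon survival, rose by 2.19, Ptprn by 2.08 and the imprinted growth inhibitor Grb10 by 2.43 (adjusted p = 2.63e-10). Srgn, a proteoglycan of secretory granules, had the largest difference, 2.77 (adjusted p = 0.00029), with a wide spread between arrays (8.12 ± 0.87 against 5.36 ± 0.78, n = 3 each, limma). The largest decreases lay in Cxcl15 (-2.16, adjusted p = 9.35e-08), Mal2 (-2.01), Adh1 (-1.69), Upk1a (-1.40), Chil1 (-1.39), Cdh3 (-1.37), Macc1 (-1.32) and the endoderm factor Foxa1 (-1.28).

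Of 52 RE1 targets, 39 rose at NP and 0 fell (41 and 0 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 5.92e-47; adjusted p = 0.137 with an estimated correlation). Of 25 pan-neuronal genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.59), with Celf5 (1.31) and the neurofilament genes Ina (1.28) and Nefh (1.17) the largest (camera adjusted p = 4.48e-15; adjusted p = 0.443 with an estimated correlation). Of 38 synaptic vesicle genes, 22 rose and 0 fell (25 and 0 adjusted over the list alone), including Rab3c (1.72) and Unc13a (1.32). The camera adjusted p was 2e-19 (adjusted p = 0.356 with an estimated correlation). Without the RE1 targets in them, 13 of 21 pan-neuronal genes (median 0.59) and 14 of 29 synaptic vesicle genes (median 0.37) rose and 0 fell. Of 29 genes of dense-core granules, 10 rose and 1 fell (13 and 1 adjusted over the list alone), with Chga at 2.04 and the prohormone convertase Pcsk1 at 1.95 (camera adjusted p = 7.53e-09; adjusted p = 0.365 with an estimated correlation). Without RE1 targets, 6 of 22 rose and 1 fell, with a median of 0.14.

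Lists of ion channels and receptors also went up in camera at NP, with most members not called. Of 37 voltage-gated channel genes, 10 rose and 0 fell (14 and 0 adjusted over the list alone), led by Hcn2 (1.32), Scn3b (1.21) and Cacng2 (1.17), with a camera adjusted p of 3.03e-10 (adjusted p = 0.438 with an estimated correlation). Of 27 glutamate genes, 7 rose, including the AMPA receptor subunit Gria2 (1.31), and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.777 with an estimated correlation). Of 23 GABA and glycine genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with the glycine receptor subunits Glra2 (1.74) and Glra1 (1.42) the largest. The camera adjusted p was 0.0219 (adjusted p = 0.777 with an estimated correlation). Chrnb2 (1.92), a nicotinic receptor subunit, and Th (1.71), the enzyme that makes L-DOPA, led the 6 of 28 cholinergic and monoamine genes that rose, while 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00349; adjusted p = 0.596 with an estimated correlation). Without RE1 targets, 8 of 34 voltage-gated channel genes (median 0.20), 6 of 26 glutamate genes (0.10), 3 of 22 GABA and glycine genes (0.11; 1 fell) and 2 of 21 cholinergic and monoamine genes (0.07) rose. Of 35 axon and adhesion genes, 12 rose and 2 fell (19 and 5 adjusted over the list alone), with Celsr3 at 1.67 and Slit1 at 1.11 (camera adjusted p = 7.31e-07; adjusted p = 0.521 with an estimated correlation).

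Of 28 Hox genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Hoxb5 at 0.61 and Hoxb6 at 0.54 (camera adjusted p = 0.041; adjusted p = 0.936 with an estimated correlation). Of 14 genes of cholesterol synthesis, 3 rose at NP (Insig1 0.55, Hmgcs1 0.40 and Idi1 0.34) and 0 fell, against 10 and 0 adjusted over the list alone (camera adjusted p = 0.000138; adjusted p = 0.777 with an estimated correlation). Of 24 fibroblast and matrix genes, 5 fell and 1 rose (7 and 1 adjusted over the list alone), among them Dcn (-1.16), Lum (-0.83), Timp1 (-0.80) and Col1a2 (-0.79). The camera adjusted p for this list was 6.01e-05 (adjusted p = 0.597 with an estimated correlation). The keratins Krt19 (-1.27), Krt8 (-0.97) and Krt18 (-0.87) were lower, whereas the endoderm list as a whole did not pass its test, with a median of 0.17 and a mean of -0.01. Of 29 cell cycle genes, 2 fell and 0 rose (3 and 0 adjusted over the list alone), Ccnd1 by -0.87 (camera adjusted p = 0.00351; adjusted p = 0.936 with an estimated correlation). Without RESTwt array b, Krt8 (adjusted p = 0.16), Krt18 (0.0901), Timp1 (0.198) and Idi1 (0.19) were no longer called, and without RESTko array a neither was Col1a2 (0.0501). Insig1, Hmgcs1 and Idi1 were not called when the fit held the NP arrays alone.

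At NP 1602 genes were called, 862 higher and 740 lower, of which 129 differed at least 2-fold, and the arrays of the groups did not overlap for 21.9% of genes, against 10% by chance. Genes of chromosome 8 made up 39.9% of the lower calls, with a median difference of -0.29 against 0.03 to 0.07 on the other autosomes. Here too the lower genes named were not sorted by chromosome, so the shift may be part of some of their differences. The count was 872 without RESTko array a and 906 without RESTwt array b, and 549 when the fit held the NP arrays alone.

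**Figure D2:**
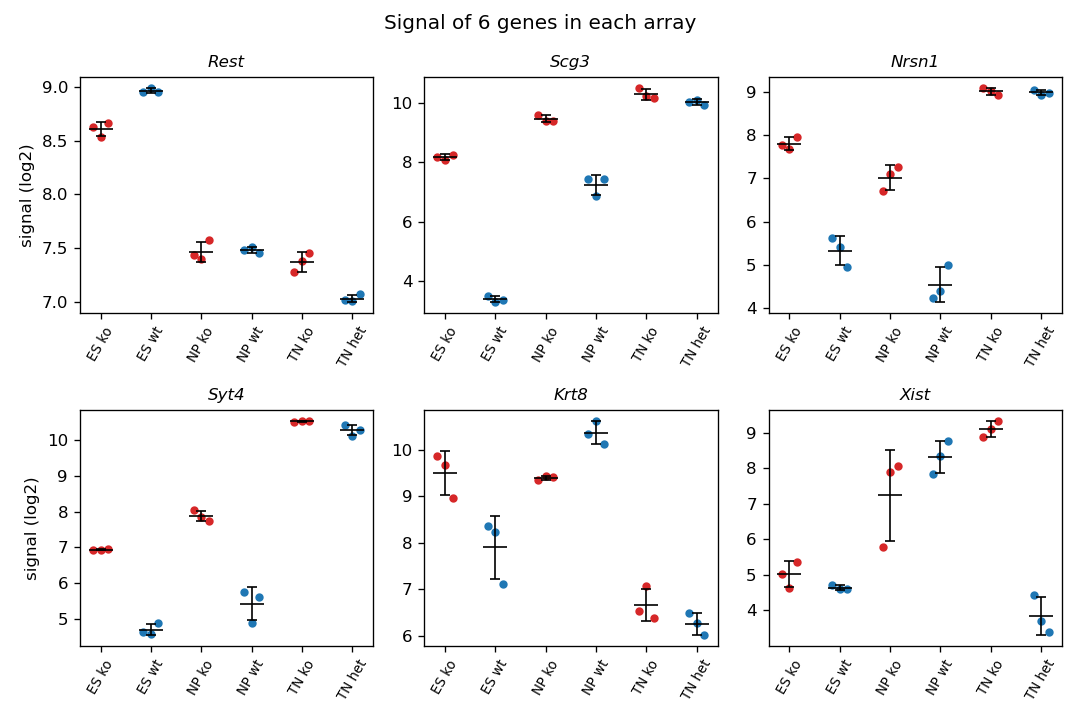
Log2 signal of Rest, Scg3, Nrsn1, Syt4, Krt8 and Xist in each of the 18 arrays (red, RESTko; blue, RESTwt or RESThet), with the mean and SD of each group of 3. Scg3 at ES lies at 8.18 in the mean of the RESTko arrays and 3.39 in the RESTwt arrays, and Xist at TN at 9.11 and 3.84.

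The comparison at TN asks which differences remain at the neuron stage, against arrays labelled RESThet. The largest was in Xist, the RNA that silences an X chromosome, at 9.11 ± 0.23 in the arrays labelled RESTko and 3.84 ± 0.54 in those labelled RESThet (difference 5.27, SE 0.42, 38.5-fold, adjusted p = 1.25e-06, limma, n = 3 each). Srgn was 9.19-fold higher (adjusted p = 0.000335), and Aqp8 (1.99), Lama1 (1.53), Rps3a1 (1.36), Epas1 (1.18), Pcdhb9 (1.11) and Sprr1a (1.07) rose. Cntnap5a, a neuronal cell adhesion gene, was 7.60-fold lower (-2.93, adjusted p = 1.13e-12). Vwc2l (-1.81), Tmem179 (-1.58), Apoa2 (-1.39), Ccl28 (-1.35) and the neuropeptide genes Trh (-1.46), Nms (-1.32) and Sst (-1.23, adjusted p = 0.0124) fell.

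Neuronal lists were not higher at TN. Of 52 RE1 targets, 1 rose (Slc18a3, 0.65) and 1 fell (Calb1, -0.55), or 2 and 2 adjusted over the list alone, with a median of 0.03 (camera adjusted p = 0.321). Of 25 pan-neuronal and 38 synaptic vesicle genes, 0 rose and 0 fell in limma. Of 29 genes of dense-core granules, Pcsk1 rose (0.91) and 4 fell, with Sst, Tac1 (-1.12) and Penk (-0.68) among them. The median of this list was 0.03 and its mean -0.11. The vesicular glutamate transporter gene Slc17a6 (-0.83), the calcium channel subunit Cacng3 (-0.73), the stem cell marker Prom1 (-0.73), the astrocyte connexin Gja1 (-0.81) and Ccnd1 (-0.61) were the only members of their lists called. These lists went down in camera: glutamate genes (adjusted p = 0.0144; adjusted p = 0.777 with an estimated correlation), voltage-gated channels (adjusted p = 0.0353; adjusted p = 0.936 with an estimated correlation), neural progenitor genes (adjusted p = 0.00349; adjusted p = 0.777 with an estimated correlation), astrocyte genes (adjusted p = 0.0165; adjusted p = 0.777 with an estimated correlation) and cell cycle genes (adjusted p = 0.00162; adjusted p = 0.936 with an estimated correlation). Oligodendrocyte genes went down as well with 0 members called, or 3 lower adjusted over the list alone (camera adjusted p = 0.0351; adjusted p = 0.777 with an estimated correlation). Without RESThet array c the calls of Sst (adjusted p = 0.051), Tac1 (0.105), Pcsk1 (0.0731), Slc17a6 (0.127), Cacng3 (0.177), Gja1 (0.149) and Ccnd1 (0.128) ended, and without RESThet array a that of Penk (0.0756).

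Endoderm and fibroblast lists were higher at TN in camera. Of 24 endoderm and epithelial markers, 3 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.26), with Lamb1 at 0.87 and Dab2 at 0.85 (camera adjusted p = 2.28e-07; adjusted p = 0.365 with an estimated correlation). Of 24 fibroblast and matrix genes, 2 rose, Ogn (0.81) and Ccn1 (0.81), and 0 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.000101; adjusted p = 0.614 with an estimated correlation). Immediate-early genes had 0 called members, or 5 higher adjusted over the list alone, with a median of 0.38 (camera adjusted p = 1.74e-06; adjusted p = 0.474 with an estimated correlation). Genes of the ER stress response had 0, or 1 higher adjusted over the list alone (median 0.16, camera adjusted p = 0.00372; adjusted p = 0.365 with an estimated correlation). Without RESThet array c the calls of Lamb1 (adjusted p = 0.182), Dab2 (0.14) and Ccn1 (0.078) ended.

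At TN 231 genes were called, 71 higher and 160 lower, of which 23 differed at least 2-fold; 2342 had an unadjusted p under 0.05. The count was 117 without RESTko array c, 138 without RESThet array c and 145 without RESTko array a. It was 50 when the fit held the TN arrays alone, a fit that ended the calls of Aqp8 (adjusted p = 0.131), Lama1 (0.108), Epas1 (0.119), Sprr1a (0.0953) and Sst (0.1). With the replicate letter as a block, in a fit that also held the TN arrays alone, the count was 27.

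The effect of the genotype differed between NP and ES for 970 genes, 461 with a more positive and 509 with a more negative effect at NP. With array weights the count was 1537. RE1 targets as a list had a more positive effect at NP (14 of 52 genes higher and 3 lower, median 0.27, camera adjusted p = 0.00045; adjusted p = 0.565 with an estimated correlation). Scg3 went against this (-2.55), as did Syp (-1.74), while Th (1.75), Mmp24 (1.42), Chgb (1.27) and Cacng2 (1.25) followed it. The effect on voltage-gated channels was more positive at NP (6 of 37 higher, 0 lower, camera adjusted p = 5.22e-05; adjusted p = 0.503 with an estimated correlation). The effects on p53 and apoptosis genes (0 higher, 3 lower, camera adjusted p = 5.34e-05; adjusted p = 0.256 with an estimated correlation) and on fibroblast genes (0 higher, 4 lower, camera adjusted p = 7.14e-06; adjusted p = 0.386 with an estimated correlation) were more negative. Krt8 (-2.57), Krt19 (-2.52), Tagln (-2.70) and Anxa3 (-2.76) carried the most negative differences beside Scg3.

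Between TN and NP the effect differed for 780 genes, 280 more positive and 500 more negative at TN. Since the controls are RESThet at TN and RESTwt at NP, the stage and the control genotype cannot be told apart here, nor can whatever the leading number in the titles marks, which also differs between the TN and NP arrays. RE1 targets led the decrease, with 31 of 52 lower and 0 higher (median -0.96, camera adjusted p = 2.86e-33; adjusted p = 0.184 with an estimated correlation), including Cplx1 (-2.43), Syt4 (-2.22), Scg3 (-1.97) and Chga (-1.90). Of 25 pan-neuronal genes 10 were lower and 0 higher (median -0.70, camera adjusted p = 1.04e-11; adjusted p = 0.365 with an estimated correlation), and of 38 synaptic vesicle genes 14 and 0 (median -0.48, camera adjusted p = 2.11e-16; adjusted p = 0.21 with an estimated correlation). Of 29 genes of dense-core granules 10 were lower and 0 higher (camera adjusted p = 4.14e-11; adjusted p = 0.21 with an estimated correlation), and of 37 voltage-gated channels 12 and 0 (camera adjusted p = 1.05e-11; adjusted p = 0.223 with an estimated correlation). Fibroblast genes moved the other way, with 6 of 24 more positive at TN (camera adjusted p = 1.78e-08; adjusted p = 0.24 with an estimated correlation), among them Dcn (1.49) and Lum (1.39). The count was 436 when the fit held the NP and TN arrays alone, 513 without NP RESTko array a, 498 without NP RESTwt array b and 503 without TN RESTko array c.

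Calls at ES and NP overlapped. Of the genes higher in the arrays labelled RESTko, 210 were called at both stages against 44.7 by chance (Fisher's exact test, adjusted p = 1.95e-85), and of the lower ones 202 (odds ratio 11.5, Fisher's exact test, adjusted p = 3.87e-113). Without chromosomes 8 and X the count for lower genes was 38. Overlaps with TN were small: 10 higher genes with ES and 12 with NP, 12 lower genes with ES and 17 with NP, against 3.68, 3.07, 6.48 and 5.94 by chance (Fisher's exact test, adjusted p = 0.0042, 9.64e-05, 0.04 and 0.000146). In the other direction, 10 of the genes higher at ES and 10 of those higher at NP were lower at TN. Since 160 genes were lower at TN and 71 higher, chance alone gives more such opposite pairs than pairs higher at both stages. No chance value was computed for the opposite pairs. Of the genes lower at ES and NP, 5 and 3 were higher at TN. Between ES and NP, 56 of the genes higher at ES were lower at NP, and 11 went from lower to higher. Across genes the effects at ES and NP correlated with r = 0.258, and genes are not independent replicates.

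The step from ES to NP asks how the cells leave pluripotency. In RESTwt cells all 27 pluripotency genes fell (median -3.11, camera adjusted p = 2.62e-11; adjusted p = 0.426 with an estimated correlation), with Tcl1 at -5.99, Zfp42 at -5.36, Tdgf1 at -5.27 and Nr0b1 at -5.26. All 25 neural progenitor genes rose, Fabp7 by 6.02, and of 28 Hox genes 25 rose and 2 fell, led by Hoxa5 at 7.15 or 142-fold (camera adjusted p = 1.4e-13 and 1.74e-12; adjusted p = 0.21 and adjusted p = 0.223 with an estimated correlation). Of 16 retinoic acid response genes 15 rose, with Rarb at 6.31 and Dhrs3 at 6.01, and this list also passed with the estimated correlation (adjusted p = 0.0253). RE1 targets rose in 34 and fell in 10 of 52 (median 0.60, camera adjusted p = 4.22e-05; adjusted p = 0.52 with an estimated correlation), and in RESTko cells in 36 and 5 (median 1.17, camera adjusted p = 1.42e-06; adjusted p = 0.511 with an estimated correlation). In RESTko cells the same 27 pluripotency genes fell and the same 25 progenitor genes rose; Hoxa5 (7.26), Dach1 (6.70) and Dcx (6.49), a protein of migrating neurons, led. In RESTwt cells 13375 genes were called, 6177 higher and 7198 lower, and in RESTko cells 13165, 6413 and 6752. With array medians subtracted the RESTwt split was 4786 and 10134 and the RESTko split 5003 and 9612, as the median of all genes moved from -0.07 to -0.25 and from -0.04 to -0.21.

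The step from NP to TN in RESTko cells asks how cells with this label mature into neurons. All 29 cell cycle genes fell (median -2.78, camera adjusted p = 2.11e-16; adjusted p = 0.357 with an estimated correlation). Of 38 synaptic vesicle genes 35 rose and 1 fell (median 2.63, camera adjusted p = 1.22e-11; adjusted p = 0.24 with an estimated correlation), with Sv2c at 5.62, and of 37 voltage-gated channels 35 rose and 0 fell (camera adjusted p = 1.03e-13; adjusted p = 0.21 with an estimated correlation), with Kcnd2 at 5.62. Slc17a6 rose by 6.90 or 119-fold, Ncam2 by 6.30, the matrix gene Postn by 6.27 and the serotonin receptor gene Htr2c by 6.25. Retinoic acid genes were among the largest decreases: Crabp2 (-6.15), Cyp26a1 (-5.51), Stra8 (-5.01) and Cyp26b1 (-4.99). In all 14147 genes were called, 8328 higher and 5819 lower. Quantile normalization again gave 5792 and 7587 and subtracting medians 5288 and 8151, as the median of all genes moved from 0.13 to -0.07 and -0.11. On this platform the titles of the TN arrays carry another leading number than those of the ES and NP arrays, the number that all arrays of the course carry too. The sources used here do not say whether it marks a batch, a cell line or something else, so neither can be told apart from the stage.

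In the mixed-strain course, which shows these steps in wildtype cells, all 27 pluripotency genes fell between ES and NP (median -5.49, camera adjusted p = 2.12e-24; adjusted p = 0.0901 with an estimated correlation), with Tdgf1 at -8.28, Pou5f1 at -7.83 and Nanog at -7.40, while Hoxa5 rose by 7.84 and Rarb by 7.49. Between NP and TN, 42 of 52 RE1 targets rose and 1 fell (median 3.31, camera adjusted p = 1.38e-18; adjusted p = 0.0928 with an estimated correlation), as did 36 of 39 synaptic vesicle genes (median 3.74, camera adjusted p = 8.6e-20; adjusted p = 0.0901 with an estimated correlation). Scn2a (7.78), Gpm6a (7.71), Tmem130 (7.63), Cntn1 (7.23) and Scg2 (7.08) rose most. Each of the 4 Rest probe sets was lower in both arrays at NP than at ES, and lower again at TN. The steps called 7071 genes (3617 higher, 3454 lower) from ES to NP, 9242 (3954 and 5288) from NP to TN and 10430 (4694 and 5736) from ES to TN. Subtracting medians moved the median of all genes from -0.09 to -0.19 and from -0.09 to -0.20 in the steps to TN. The step from ES to NP correlated across genes with that of the RESTwt cells at r = 0.773.

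Genes that differed at NP were often those that change in the course. Of 829 genes higher in the arrays labelled RESTko at NP and measured on both platforms, 596 or 71.9% rose between ES and TN of the course, against 27.3% of all 16553 genes (Fisher's exact test, adjusted p = 1.33e-165). Of the genes higher at ES, 38.5% rose and 41.0% fell there, and of those lower at NP 20.6% rose and 51.9% fell, against 33.3% of all genes that fell. Without the dimmest 30% of genes the share of those higher at ES that rose was 40.2%, against 36.2% of all genes. Of 149 genes lower at TN, 65 or 43.6% rose (Fisher's exact test, adjusted p = 2.97e-05), and of those higher at TN 24.6% did (Fisher's exact test, adjusted p = 0.678). The excess among genes lower at TN was lost without the dimmest 30% of genes (40.3% against 36.2%, Fisher's exact test, p = 0.357).

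**Figure D3:**
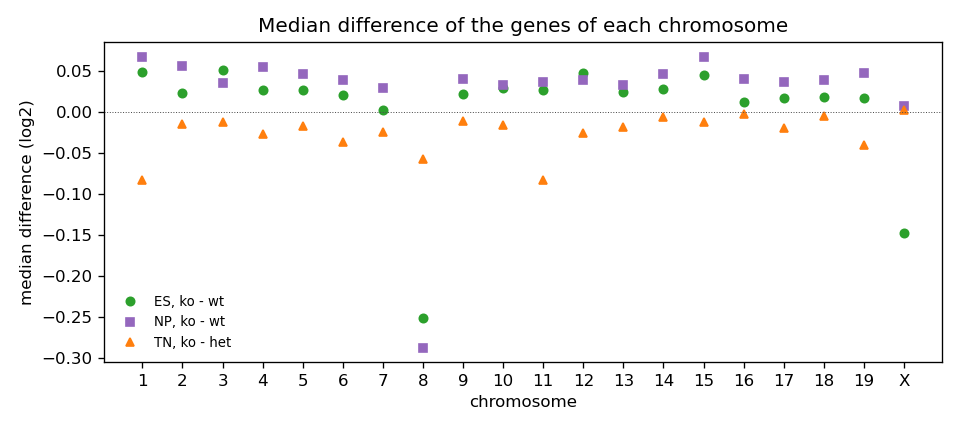
Median log2 difference (RESTko minus RESTwt at ES and NP, RESTko minus RESThet at TN, 3 arrays per group) of genes in the upper part of the signal range, by chromosome. Chromosome 8 lies at -0.25 at ES and -0.29 at NP, and at -0.06 at TN, where chromosomes 1 and 11 lie at -0.08.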

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

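The tests of the copies of chromosome 8, of loss of REST at chromosome 8, of REST as a repressor of Xist, of a Y chromosome, of the share of neurons and of repression at RE1 targets were chosen only after the result was seen; the others were set beforehand.

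The effect of the genotype differed between NP and ES for 970 genes by a test of the difference itself. The 5 genes with the most positive difference were Kbtbd11 (3.13), Slitrk1 (2.11), Fstl5 (2.11), Ogdhl (1.86) and Iqsec3 (1.79), and the 5 with the most negative Anxa3 (-2.76), Tagln (-2.70), Krt8 (-2.57), Scg3 (-2.55) and Krt19 (-2.52). The effect differed between TN and NP for 780 genes, with Xist (6.34), Cxcl15 (2.35), Sprr1a (2.25), Mal2 (1.96) and Adh1 (1.94) the most positive and Cntnap5a (-2.93), Nrsn1 (-2.45), Grb10 (-2.45), Cplx1 (-2.43) and Nmnat2 (-2.22) the most negative. Probes with no single gene symbol, which no comparison of genes used, also differed between genotypes in a fit of all probes together. At ES 383 were called, or 2.78% of 13767 against 7.06% of the probes with a single symbol in the same test. At NP 280 were called (2.03% against 5.46%) and at TN 151 (1.10% against 0.913%).

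Other splits of the same arrays were counted for each comparison. For the difference between NP and ES, 2 of 100 splits gave as many genes as the real 970, a share under 0.05. The other of these, with 2308 genes, keeps both genotype groups whole and exchanges them at 1 stage, so that it tests the sum of both effects. All remaining splits mix arrays of both genotypes within a stage, which adds the genotype effects to the spread. The low share therefore cannot exclude chance. For the difference between TN and NP, 1 of 100 splits gave as many genes as the real 780, the real one itself, with at most 545 in the others. The exchange of the genotype groups at 1 stage, which was not among the splits drawn here, tests the sum of both effects and calls 823 genes. The splits drawn mix genotypes in the same way as above, so chance cannot be excluded here either. The 10 splits of 3 arrays against 3 are too few for a share under 0.05: in each comparison 1 of 10, the real one, gave as many genes, with 1842 against at most 1 at ES, 1602 against 5 at NP and 231 against 5 at TN. For the stage steps the values were 13375, 13165 and 14147 against 0. The other splits here mix the compared groups as well, which adds their difference to the spread and lowers the count. The low counts therefore cannot exclude chance.

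Genes of chromosome 8 were lower in the arrays labelled RESTko at ES (median -0.25) and NP (-0.29), with 250 and 295 of 961 genes called lower. The arrays' normalization is argued against only in part. After quantile normalization again, chromosome 8 still lay 0.231 below the lowest other autosome at ES and 0.321 at NP. Subtraction of medians moves all genes of an array alike, so it could not change this distance. The normalization behind the deposited values is not given and could not be undone. A difference in copies of chromosome 8 between the cultures is a candidate explanation, since each of 10 stretches along the chromosome was lower, the least of them by -0.20. Loss of REST itself stays open, because at TN the chromosome differed from the others by -0.0307, yet the control there is another genotype. Genes of chromosome X were also lower at ES, with a median of -0.15, but not at NP (0.01). At TN chromosomes 1 and 11, each with a median of -0.08, lay lower than chromosome 8 (-0.06). Of their genes in the upper part of the signal range, 76.9% and 76.8% lay below zero, against 69.1% on chromosome 8. The cause was not tested.

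Xist was 38.5-fold higher in the arrays labelled RESTko than in those labelled RESThet at TN. The idea that REST keeps Xist low at every stage is argued against by NP, where Xist stood at 7.85 to 8.76 in the arrays labelled RESTwt, the lowest of them 3.42 above the highest RESThet array at TN, while an effect at TN alone stays open. The genotypes did not differ past the threshold at NP (-1.07, SE 0.42, adjusted p = 0.153, limma), and RESTko array a carried much of that value (-0.33, SE 0.27, adjusted p = 0.679 without it). A Y chromosome in 1 group only is argued against by 3 Y-linked genes, which differed by at most 0.22 and lay between 2.30 and 3.30 in every array. A single X chromosome in the RESThet cells may account for the pattern and cannot be told apart from other causes, since 4 genes that escape silencing differed by a median of 0.0503, which lies between the bounds set for either outcome.

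Genes higher in the arrays labelled RESTko at NP were mostly genes that rise in neurons. A larger share of neurons in those cultures is argued against as the whole cause: genes matched to the RE1 targets for their rise in the course and their level at NP had a median difference of 0.20, against 0.98 for the targets, and 47 of 51 targets lay above their matches. The matching was changed after a pooled form, with a weaker rise of 2.34 against 3.32, had given 0.12. A larger share of neurons stays open as a part of the cause. The RE1 list may lack targets, so genes outside it cannot separate this from lost repression. Of the 414 matched genes, 76 were called higher and 14 lower. Pan-neuronal genes outside the RE1 list had a median of 0.59 (13 of 21 higher, 0 lower), and synaptic vesicle genes 0.37 (14 of 29 higher, 0 lower). At ES the same genes had medians of 0.20 (7 of 21 higher, 0 lower) and 0.014 (5 of 29 higher, 1 lower). Fewer non-neural cells stay open, because pan-neuronal genes lay 0.40 above neural progenitor genes while fibroblast markers fell. Loss of repression at RE1 targets is a candidate explanation, since 22 of the 52 targets were called higher and 0 lower at ES, with a median of 0.23, although the others were not called there.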

How the results depend on the processing

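The settings that leave out the genes of chromosomes 8 and X and the plain letter block of the course were chosen only after the result was seen. Of the called genes, 1 at ES and 1 at NP changed sign with the mean over probes, in neither case past the threshold, and 0 did at TN. Under the other settings that test genes 0 did at any of the 3 stages. Fits on the compared groups alone, the letter block, trend and robust, and omission of dim genes or of chromosomes 8 and X keep the difference of group means. No sign could change under them. Leaving out 1 array at a time gave 1190 to 1777 genes at ES, 872 to 1776 at NP, 117 to 205 at TN, 651 to 1136 for the difference between NP and ES, 498 to 928 for that between TN and NP, 12479 to 13008 and 12259 to 12512 for the steps from ES to NP in RESTwt and RESTko, 13301 to 13700 for the step to TN in RESTko, and 5335 to 5839, 8193 to 8694 and 9390 to 9978 for the steps of the course. A 2-fold minimum left 149 genes at ES, 129 at NP, 23 at TN, 221 and 182 for the differences, 3522, 3814 and 4430 for the stage steps and 3215, 5401 and 6896 in the course, by its own construction. An adjusted p under 0.01 left 971, 746, 87, 421 and 274 in the genotype comparisons and their differences. Testing every probe gave 350 at TN, 20240, 19801 and 22461 for the stage steps and 13013, 18980 and 21848 in the course, with more items tested. Of the 350 at TN, 151 were probes with no single gene symbol. Fits on the compared groups alone gave 549 at NP, 50 at TN and 436 for the difference between TN and NP, with fewer arrays to estimate the spread. Array weights gave 3430 at ES and 1537 for the difference between NP and ES; the cause was not tested. The replicate block gave 27 at TN, in a fit of the TN arrays alone, which gave 50 without the block. The replicates share only a letter, with a correlation over 0.1 in 4 of 9 pairs (NP a 0.40 and NP b 0.31 the highest) and the best match to their own letter in 2. Of 29 list calls, 0 were left with an estimated correlation; fry called 15 lists, 12 of them among the 29. With a 2-fold minimum the overlaps were 28 and 1 (ES and NP, higher and lower), 0 and 0 (ES and TN) and 1 and 0 (NP and TN), with few genes left; without chromosomes 8 and X the lower overlap of ES and NP was 38. In the course the share of genes lower at ES that rose was 10.7% with the 2-fold minimum, which turned its direction, and 37.9% without dim genes; the share for genes lower at NP was 8.82% with the 2-fold minimum and for those lower at TN 40.3% without dim genes, against 36.2% of all genes (Fisher's exact test, p = 0.357); the cause was not tested. With the mean over probes, Usp15, lower in both steps to TN of the course as reported (-0.51 and -1.64), turned to 0.89 from NP and 0.26 from ES; the cause was not tested. The platform of the genotype comparisons has 1 Rest probe set, so testing every Rest probe gave no other value. A letter block within stages could not be fitted in the course.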

Other observations

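The count of genes called at all 3 stages was chosen only after the result was seen; the gene lists were fixed beforehand.

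Of 17 imprinted and germline genes, 6 were higher and 4 lower at ES in the arrays labelled RESTko (8 and 5 adjusted over the list alone), and the list did not pass its test (camera adjusted p = 0.112), with the growth inhibitor Grb10 (1.25), the growth factor Igf2 (1.02) and Peg10 (0.75) among the higher and the germ cell gene Dazl (-0.77) among the lower. At NP Grb10 (2.43) and the cell cycle inhibitor Cdkn1c (1.26) rose and Peg3 (-0.85) fell. Their effects differed between TN and NP, by -2.45 for Grb10, -1.52 for Cdkn1c and 0.97 for Peg3. Of 28 genes of dorsoventral and regional patterning, 3 rose at NP and 1 fell (4 and 1 adjusted over the list alone), with Olig3 at 1.74 and Wnt1 at 0.81, and the list did not pass its test (camera adjusted p = 0.54). Of 20 genes near Rest on its chromosome, 4 were higher at ES and 0 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.317, not passed): Kit (0.91), Noa1 (0.79), Polr2b (0.34) and Srp72 (0.24), the last of which was not called without RESTwt array c (adjusted p = 0.244).

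Called at all 3 stages were 4 genes higher in the arrays labelled RESTko (Kdelr3, Mzt1, Pcsk1 and Pibf1) and 4 lower (Ccdc124, Ccnd1, Ndufs5 and Ufsp2). These genes were not sorted by chromosome, while genes of chromosome 8 made up 30.9% of the lower calls at ES and 39.9% at NP. A shift of a whole chromosome can therefore be part of such agreement between stages. The prohormone convertase Pcsk1 rose by 0.83, 1.95 and 0.91 at ES, NP and TN, and the cyclin Ccnd1 changed by -0.48, -0.87 and -0.61. Leaving out single arrays ended the call of Pcsk1 at TN (adjusted p up to 0.0866, without RESTko array a) and of Ccnd1 at ES (up to 0.0826, without RESTko array b) and TN (up to 0.128, without RESThet array c).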
